A study of Mus musculus with 28 samples.

How the data were processed

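RNA was sequenced from the ventromedial prefrontal cortex of 28 individual female mice in 4 groups of 7. Each mouse had received a virus carrying LacZ, the control, or a virus labelled as a Slit1 knockdown, and was taken at baseline or after 3 days of a stress procedure abbreviated sCVS, per the labels. Tissue was punched with a blunt needle from coronal slices 1 mm thick and viral placement was checked by fluorescence, per the labels' protocols. Libraries were made from 1 µg of ribosome-depleted total RNA with random hexamer priming and a strand-specific kit, with 7 libraries per lane, paired reads given as 260 bp and about 35 M reads per sample, per the labels' protocols. Counted fragments after removal of duplicates reached 44.3 M, more than the 35 M reads stated, and whether 260 bp is a read or a fragment length was not given, so these protocol values are uncertain. Which libraries shared a lane was not given in the sources used here, so no lane could be entered as a batch.

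The deposited values were raw counts of fragments per gene for each library, made with featureCounts 1.6.2 over whole gene spans with the Ensembl release 90 annotation of GRCm38, per the file headers. Read pairs were counted as fragments, no strand option was set, and the alignment names say that the reads were sorted and that duplicates were removed, per the file headers. HISAT2, featureCounts, Subread and DESeq2 were named with the mm10 and GRCm38 builds, per the submitters' processing notes. These settings shape the measurements in 3 ways. A count over a whole span includes reads from introns of unspliced RNA, so long genes carry much intronic signal. Without strand, reads of a gene and of its antisense partner cannot be told apart. Fragments lying in overlapping genes were counted for neither, so of the 12185 genes that lie entirely inside another gene, 1265 of them protein-coding, 99.9% were at 0 in every library, against 18.1% of all other genes. Of the gene group members, 35 were lost in this way, among them Gfap, B2m, P2ry12, Itgam and Cxcl10, and a gene listed at 0 for this reason was not shown to be absent.

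The files held 52636 genes, of which 52489 identifiers were matched to symbols. Total counts ran from 30.6 M to 44.3 M per library with a median of 39.6 M, and 20882 to 26156 genes had at least 1 count. No pair of libraries held identical counts, and the closest pair differed by a chi-square of 27.2 per gene, far above sampling noise, so all 28 were kept as separate samples. Genes were kept by filterByExpr by group, which left 19171. Counts were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust) in R 4.3.3, with 1 coefficient per group over all 28 libraries and no covariates. The common biological coefficient of variation was 0.467. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Levels are depth-scaled counts (CPM) of the TMM-scaled library as mean ± SD of 7 libraries, log2 fold changes are given with their standard error, and log2 CPM used a prior count of 2.

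Comparisons were of the knockdown label within each stress state, of stress within each virus, of their interaction, and of both effects averaged over the other factor. The groups, comparisons, tests, gene groups, named genes and all alternatives except those marked otherwise were chosen before the data were examined. In each comparison the genes named were Slit1 to Slit3 and Robo1 to Robo4, with Fkbp5, Sgk1, Tsc22d3, Fos and Arc for stress and Gfap, Aif1, Cd68 and Isg15 for the knockdown label. To these were added the 12 genes with the smallest p that rose and the 12 that fell, and up to 4 passing members per gene group. Where fewer than 10 passed, the 10 genes with the smallest p were named instead, leaving out predicted genes. Members given as examples of a gene group outside this rule were picked after their values were seen. Slit1 was also compared between groups of 7 with a two-sided exact permutation test of mean log2 CPM over all 3432 splits, whose smallest possible p is 5.83e-04.

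Gene groups were 44 lists with 1021 members, 963 of them tested, covering axon guidance, receptors and channels, stress and activity responses, immune and metabolic pathways, and cell type markers. Beside the Slit and Robo genes, the list named the Slit and Robo family held Srgap1, Srgap2, Srgap3, Nell2, Flrt3, Dag1 and Dcc. They were tested with camera in limma 3.58.1 on voom values with the inter-gene correlation estimated for each list, and with Benjamini-Hochberg adjustment over the lists of a comparison. Alternatives were DESeq2 1.42.0, limma voomWithQualityWeights, RLE and upper-quartile factors, no count filter, a CPM of at least 1 in 7 libraries, fits of only the 2 groups compared, an adjusted p under 0.1, an unadjusted p under 0.05 with a fold change of at least 1.3, and each library left out in turn. As covariates were tried mouse numbers above 20 in the titles, up to 3 surrogate variables from sva 3.50.0 (2 were found), and the mean levels of the oligodendrocyte and striatal lists. For the gene groups, camera with a preset correlation of 0.01 and fry were run.

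Chosen after seeing the data were a fit with the trend of each library on exonic GC content removed by offsets (loess, span 0.4, values for 99.7% of genes), fits without 2 libraries that stood apart, fits with the 7 places in the accession order as blocks, splits of the stress labels within these places, the gene groups with each library left out, and marker lists of bone, marrow granulocytes and skeletal muscle. The GC slope of a library is the log2 deviation from the mean library per 10 percentage points of GC, fitted over genes with a mean log2 CPM above 1. The steps were tested on simulated data and on real counts thinned, and so lowered, for genes drawn at random from those with higher mean counts. Recovery in thinned counts therefore does not stand for all tested genes. In the thinned counts for the knockdown label without stress, edgeR recovered 13.4% of genes changed 1.5-fold, 50.7% of those changed 2-fold and 80.3% of those changed 4-fold. For the knockdown label averaged over both stress states these shares were 31.3%, 83.6% and 90.9%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.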

Results

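Gene expression was measured by RNA sequencing in the ventromedial prefrontal cortex, a cortical region involved in emotional control, of 28 female mice. The series title names a role of SLIT1, a secreted axon guidance protein, in susceptibility to stress. The 4 groups of 7 mice were LacZ unstressed, LacZ stressed, Slit1 knockdown unstressed and Slit1 knockdown stressed, where LacZ was the control virus and stress lasted 3 days. Mice are separate animals per the labels, so the spread between libraries holds animal, dissection and library differences together. Total counts averaged 38.1 ± 3.48 M (SD, n = 7) in LacZ unstressed, 38.4 ± 3.37 M in LacZ stressed, 39.2 ± 4.58 M in knockdown unstressed and 39.2 ± 3.43 M in knockdown stressed libraries.

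The targeted gene was examined first. Slit1 (ENSMUSG00000025020, GRCm38 chromosome 19, 41600257 to 41743665, minus strand) encodes a ligand of the Robo receptors. Its level without stress was 24.4 ± 16.1 CPM (SD, n = 7) in LacZ libraries, from 12.6 to 56.3, and 25.9 ± 17.5 CPM (SD, n = 7) in libraries labelled Slit1 knockdown, from 9.48 to 59.9 (exact permutation p = 0.919). With stress it was 19.8 ± 10.2 CPM (SD, n = 7) in LacZ libraries, from 9.28 to 33.9, and 18.2 ± 9.81 CPM (SD, n = 7) in libraries labelled knockdown, from 7.48 to 30.9 (exact permutation p = 0.716). Of the libraries labelled knockdown, Slit1 in 5 of 7 unstressed and 4 of 7 stressed ones lay below the LacZ mean in CPM, and in 3 of 7 and 4 of 7 below the mean of log2 CPM. Over both stress states its log2 fold change was -0.02 with a 95% confidence interval from -0.64 to 0.60, which allows a reduction of up to 35.6%. The counts therefore did not show a lower Slit1 in the libraries labelled Slit1 knockdown, and every direction given for that label rests on the label alone. The counted span is 143409 bp, of which 5921 bp (4.13%) are exonic, so intronic reads enter the level of this gene. Omitting LacZ unstressed replicate 1 moved the log2 fold change over both stress states to 0.16, and omitting knockdown unstressed replicate 2 moved it to -0.20.

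**Figure D1:**
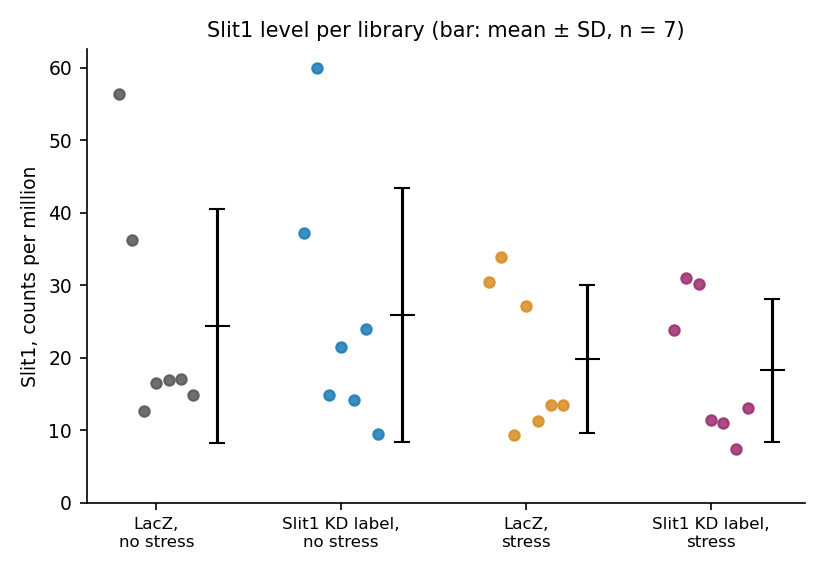
Slit1 level in depth-scaled counts (CPM) for each of the 28 libraries by group, with the mean and SD of each group of 7. Libraries labelled Slit1 knockdown spread over 9.48 to 59.9 CPM without stress and 7.48 to 30.9 CPM with stress, overlapping the LacZ libraries.

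Libraries differed in ways that the groups did not follow. The first principal component of log2 CPM held 58.8% of the variance and the second 14.7%, and the 4 groups accounted for 0.185% of the variance of the first (permutation p = 0.997). Over the 28 libraries this component moved with the slope of a library on exonic GC content, with Pearson's r = 0.995 and Spearman's rho = 0.995, and with r = 0.995 without the 2 libraries farthest from the median. The GC slope, from -1.34 to 1.36, also moved with the share of counts from mitochondrial genes (r = -0.841, rho = -0.883, r = -0.827 without the 2 farthest libraries). It moved too with the log2 CPM of Slit1, whose exons have 59% GC (r = 0.896, rho = 0.856, r = 0.874 without the 2 farthest). Each of these had a permutation p of 1.00e-05, the smallest that the permutations can give, and an adjusted p of 1.75e-05 by Benjamini-Hochberg over 14 relations. With group means removed, r was 0.996, -0.851 and 0.920 in the same order. The libraries farthest from the median were LacZ unstressed replicate 1 and knockdown unstressed replicate 7. The log2 total count also moved with the first component, less closely (r = 0.569, rho = 0.570, permutation p = 0.00148 for r, adjusted p = 0.00173 by Benjamini-Hochberg). Without knockdown unstressed replicate 7 and LacZ unstressed replicate 3, the farthest in total count, r was 0.491. Replicate numbers give the place of a library in the accession order of its group. No label calls this place a batch. With group means removed, the 7 places held 70.1% of the variance of the component (permutation p = 0.00107). They held 71.6% of that of the GC slope (permutation p = 7.50e-04) and 64.8% of that of the mitochondrial share (p = 7.00e-04), against 18.3% for total counts (p = 0.669). The mean GC slope was 0.94 and 0.73 at places 1 and 2 and -0.75 at place 7.

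**Figure D2:**
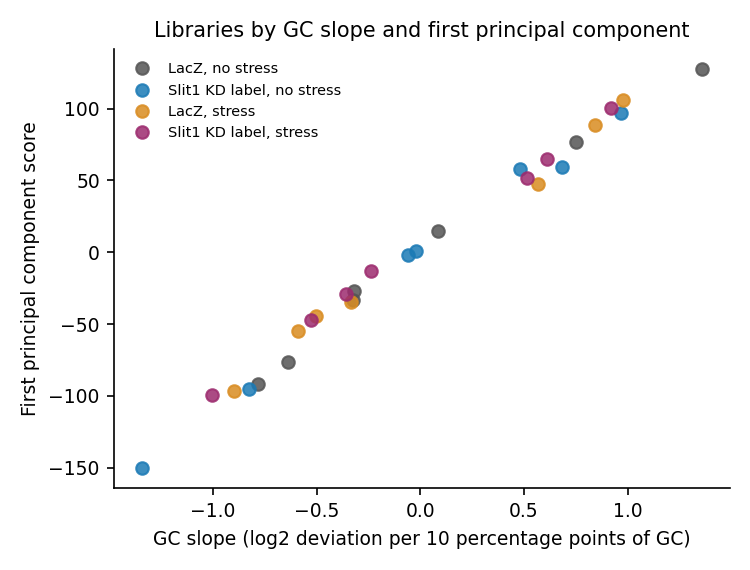
Score on the first principal component of each of the 28 libraries against its GC slope, the log2 deviation from the mean library per 10 percentage points of exonic GC content, coloured by group. The libraries lie along a line with r = 0.995, and each group is spread along it.

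Some single libraries differed widely from the rest of their group in sets of transcripts. In knockdown stressed replicate 2, genes of bone stood far above all other libraries. Ibsp, a protein of mineralised matrix, had 218.1 CPM there from 9619 fragments, against 3.02 CPM in the next highest library. Col1a1 and Col1a2, the chains of type I collagen, had 633.5 and 998.6 CPM against 10.3 and 31.1 CPM. Mmp13, Ctsk and Mmp9, which encode proteases of bone turnover, had 223.5, 252.0 and 95.5 CPM against 2.04, 6.02 and 1.32 CPM. The next highest library was knockdown unstressed replicate 6 for these genes except Mmp13. In LacZ stressed replicate 4, transcripts of cytotoxic T cells and of inflammation were nearly missing. Cd8a had 2 fragments, the granzyme gene Gzmb 18, the acute phase gene Saa3 2 and the interleukin antagonist gene Il1rn 3. In CPM these were 0.0453, 0.408, 0.0453 and 0.0680, where the median library had 9.58, 44.9, 8.87 and 14.6 CPM. Markers of striatal neurons, among them the dopamine receptor gene Drd2, were highest in knockdown stressed replicate 7, at 17.5 CPM against a median of 1.56.

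**Figure D3:**
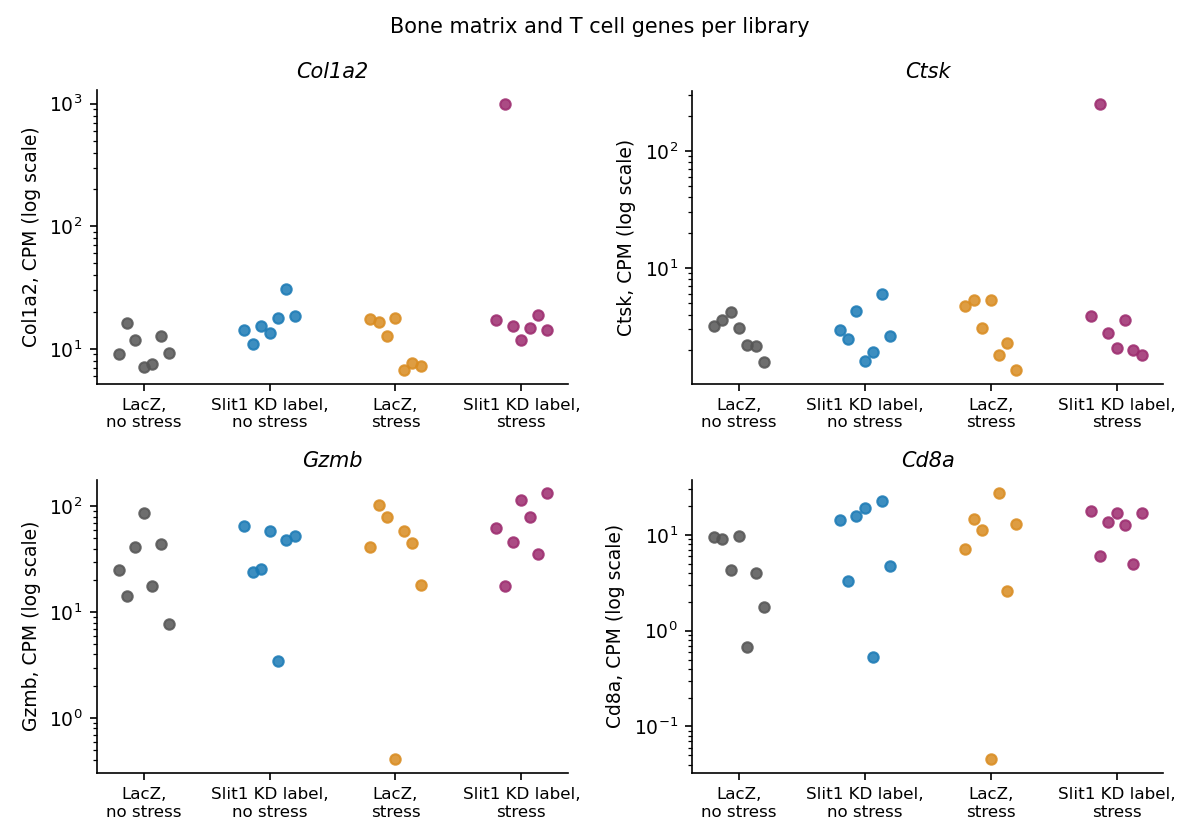
Level of Col1a2, Ctsk, Gzmb and Cd8a in each of the 28 libraries by group, in CPM on a log axis, with each point a library. Col1a2 and Ctsk stand out in knockdown stressed replicate 2, at 998.6 and 252.0 CPM, and Gzmb and Cd8a are lowest in LacZ stressed replicate 4, at 0.408 and 0.0453 CPM.

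The first comparison asked what the knockdown label did without stress. The genes with the smallest p included Itih5 (chromosome 2, 10153571 to 10256529), which encodes a hyaluronan-binding matrix protein, with 36.5 ± 6.05 CPM (SD, n = 7) in libraries labelled knockdown and 27.7 ± 3.19 CPM (SD, n = 7) in LacZ libraries. Its log2 fold change was 0.39 ± 0.13 (SE), above the LacZ mean of log2 CPM, the scale of all such counts of libraries that follow, in 7 of 7 libraries. Pmp22, a myelin protein gene, had 0.48 ± 0.17, and Ttr, the thyroid hormone carrier made by choroid plexus, 1.39 ± 0.49 at a mean of only 0.488 CPM. Lower values were seen for Tfap2d, a transcription factor gene, at -1.79 ± 0.56, for Lipt1, which acts in lipoic acid transfer, at -0.67 ± 0.22, and for Mrpl30, a mitochondrial ribosome protein gene, at -0.31 ± 0.11. Snu13, a spliceosome component, had -0.35 ± 0.12, the actin-related gene Actrt3 -0.82 ± 0.29, the kinase gene Nrk 1.25 ± 0.43 and the minor spliceosome RNA Rnu12 1.15 ± 0.37. Tfap2d was -1.05 without LacZ unstressed replicate 4, and Rnu12 was 0.66 without knockdown unstressed replicate 6. None of these 10 genes passed (adjusted p = 1 for each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

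In the Slit and Robo family without stress, the knockdown label gave log2 fold changes of 0.09 ± 0.43 (SE) for Slit1, -0.02 ± 0.29 for Slit2, 0.21 ± 0.23 for Slit3, 0.11 ± 0.23 for Robo1, 0.03 ± 0.31 for Robo2, -0.41 ± 0.45 for Robo3 and 0.11 ± 0.36 for Robo4. Markers of microglia and of interferon response were also within error, with 0.17 ± 0.41 for Aif1, 0.35 ± 0.62 for Cd68 and 0.47 ± 0.70 for Isg15. Gfap, the astrocyte filament gene, was listed at 0 in all libraries because its span lies 100% inside another annotated gene. Of the gene groups, cholesterol synthesis had 22 of 23 members below 0 (median log2 fold change -0.21, adjusted p = 0.231 by camera), with Sqle at -0.21 ± 0.18 and Insig1 at -0.28 ± 0.20. Oligodendrocyte precursor markers had 9 of 13 members above 0 (median 0.18), and neuropeptides had 11 of 16 below 0 (median -0.16), both also at an adjusted p of 0.231 by camera. Nuclear subunits of oxidative phosphorylation had 41 of 43 members below 0 (median -0.21, adjusted p = 0.344 by camera). Single libraries carried much of these: the median was -0.02 for neuropeptides and -0.09 for oxidative phosphorylation without LacZ unstressed replicate 1, and 0.10 for oligodendrocyte precursors without LacZ unstressed replicate 7. In this comparison 0 of 19171 genes and 0 of 44 gene groups passed. The number of genes at an unadjusted p under 0.05 was 172 by edgeR, 253 by DESeq2 and 704 by voomWithQualityWeights. The latter 2 tools also called 0 genes after adjustment. Evenly spread p would give 959, but regrouped virus labels did not. Of 100 splits, the real one included, 83 gave 172 genes or more by edgeR. The median of the splits other than the real one was 514. These splits did not keep the accession order, whose places held much of the first component, so they are not a matched reference for this count.

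With stress, the genes with the smallest p for the knockdown label were led by genes of bone, whose high values came from knockdown stressed replicate 2. The log2 fold changes were 8.33 ± 1.81 (SE) for Ibsp, 5.93 ± 1.47 for Col1a1, 5.59 ± 1.35 for Mmp9, 5.38 ± 1.36 for Mmp13, 4.96 ± 1.11 for Atp6v0d2, a proton pump subunit of osteoclasts, 3.67 ± 0.86 for Col1a2, 3.49 ± 0.94 for Ctsk and 2.44 ± 0.64 for Col13a1. Without that library they were 0.95 for Ibsp, -0.21 for Col1a1, 0.03 for Mmp9, -0.06 for Mmp13, 1.29 for Atp6v0d2, 0.33 for Col1a2, -0.34 for Ctsk and 0.82 for Col13a1. The other 2 of the 10 genes were Tmem26, a membrane protein gene, at 1.00 ± 0.27, and Adam12, a metalloprotease gene, at 1.04 ± 0.30, both above the LacZ mean in 7 of 7 libraries, and they were 0.85 and 0.63 without the bone-rich library. None of the 10 passed (adjusted p = 1 for each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Adjusted over the list alone, 3 genes of the extracellular matrix list, Mmp9, Col1a2 and Col1a1, passed (adjusted p = 0.00334 for each by edgeR with Benjamini-Hochberg), and 2 of them, Col1a2 and Col1a1, passed in the meninges and fibroblast list, against 0 over all genes.

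For the knockdown label with stress, Slit1 had -0.12 ± 0.43 (SE), Slit2 0.09 ± 0.29, Slit3 0.21 ± 0.23, Robo1 0.03 ± 0.23, Robo2 0.03 ± 0.31, Robo3 -0.64 ± 0.45 and Robo4 -0.19 ± 0.36. The microglial genes Aif1 and Cd68 had 0.29 ± 0.41 and 0.20 ± 0.62, and Isg15 had -0.51 ± 0.69. Glucocorticoid-responsive genes had 18 of 26 members above 0 (median 0.14, adjusted p = 0.0889 by camera), among them Fkbp5, a regulator of the glucocorticoid receptor, at 0.45 ± 0.18, and Hif3a at 0.67 ± 0.32. Meninges and fibroblast markers had 16 of 17 members above 0 (median 0.56, adjusted p = 0.205 by camera), and excitatory neuron markers 15 of 15 below 0 (median -0.28, adjusted p = 0.207 by camera). Immediate early genes had 21 of 28 members below 0 (median -0.20, adjusted p = 0.356 by camera). Without 1 library the medians came closer to 0: 0.08 for glucocorticoid-responsive genes (knockdown stressed replicate 3), 0.07 for meninges (knockdown stressed replicate 2), -0.14 for excitatory neurons (knockdown stressed replicate 7, rich in striatal markers) and -0.10 for immediate early genes (LacZ stressed replicate 1). By edgeR 0 of 19171 genes passed, with 158 at an unadjusted p under 0.05, and DESeq2 and voomWithQualityWeights called 0 with 175 and 880 at that level. None of the 44 lists passed, but the count was sensitive to single libraries: it was 1 without LacZ stressed replicate 1, 1 without knockdown stressed replicate 1, 2 without LacZ stressed replicate 4 and 2 without knockdown stressed replicate 4. Without both knockdown stressed replicate 2 and LacZ stressed replicate 4 it was 3, with glucocorticoid-responsive genes and meninges markers up and deep cortical layer markers down (smallest adjusted p = 0.0263 by camera).

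Averaged over both stress states, the 10 genes with the smallest p all had positive log2 fold changes for the knockdown label, and none passed. Having been picked by p, they lie to one side of the LacZ mean in many libraries by selection. Itih5 had a log2 fold change of 0.35 ± 0.09 (SE), above the mean of all LacZ libraries in 13 of 14 libraries. Ptpn13, a tyrosine phosphatase gene, had 0.27 ± 0.07 in 13 of 14, and Scn11a, a sodium channel gene of sensory neurons at group means of 0.610 CPM or less, 0.97 ± 0.25 in 14 of 14, and 0.70 without knockdown stressed replicate 2, where it was highest at 1.72 CPM. Spp1, the secreted phosphoprotein osteopontin, had 1.44 ± 0.41 in 13 of 14 and 0.83 without that library, while Ibsp and Mmp9 were above it in 8 of 14. The same omission took Ibsp from 4.86 to 1.17, Col1a1 from 3.71 to 0.64, Col1a2 from 2.19 to 0.52, Atp6v0d2 from 2.78 to 0.94, Col13a1 from 1.59 to 0.78 and Mmp9 from 3.05 to 0.27. The adjusted p was 1 for all 10 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Adjusted over the list alone, Spp1 passed in the complement and phagocytosis list (adjusted p = 0.0410 by edgeR with Benjamini-Hochberg), against 0 over all genes. So did 3 genes of the extracellular matrix list (Mmp9, Col1a2 and Col1a1) and 2 of the meninges and fibroblast list (Col1a2 and Col1a1), all bone genes of that library.

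For this average, Slit1 had -0.02 ± 0.30, Slit2 0.04 ± 0.20, Slit3 0.21 ± 0.17, Robo1 0.07 ± 0.16, Robo2 0.03 ± 0.22, Robo3 -0.53 ± 0.32 and Robo4 -0.04 ± 0.25, and the glial and interferon genes had 0.23 ± 0.29 for Aif1, 0.28 ± 0.44 for Cd68 and -0.02 ± 0.49 for Isg15. Glucocorticoid-responsive genes had 18 of 26 members above 0 (median 0.10, adjusted p = 0.163 by camera), with Fkbp5 at 0.39 ± 0.12 and Mertk, a phagocytic receptor gene, at 0.24 ± 0.09. Cholesterol synthesis had 23 of 23 members below 0 (median -0.18, adjusted p = 0.189 by camera). Microglial markers had 13 of 16 above 0 (median 0.14, adjusted p = 0.417 by camera), with a median of 0.02 without knockdown stressed replicate 3. The glucocorticoid median was 0.06 without knockdown unstressed replicate 6. The interferon response list had 24 of 38 below 0 (median -0.02, adjusted p = 0.614 by camera, whose direction was up). No gene of 19171 and no list passed: edgeR, DESeq2 and voomWithQualityWeights called 0 genes, with 291, 373 and 1224 at an unadjusted p under 0.05. The count of lists was 1 without LacZ stressed replicate 1, 1 without knockdown stressed replicate 1 and 2 without LacZ stressed replicate 4.

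Stress was then compared with no stress under the control virus. Among genes with the smallest p, Slc35g1, a membrane transporter gene, had a log2 fold change of 0.56 ± 0.22 (SE), with 6.16 ± 1.89 CPM in stressed and 4.16 ± 0.935 CPM in unstressed LacZ libraries (SD, n = 7), above the unstressed mean in 7 of 7. Trbc2, a T cell receptor constant region, had 0.72 ± 0.27 and Kif11, a mitotic kinesin gene, 1.62 ± 0.62, each above it in 6 of 7. Dlx1as, an antisense RNA of an interneuron transcription factor gene, had -0.44 ± 0.16, but 68.2% of its span overlaps other genes and the counts ignore strand. H2-M2 had 1.41 ± 0.52, Gcc2 -0.87 ± 0.33, Ttc29 -1.64 ± 0.64, Tmbim7 -0.88 ± 0.35, Tdrd12 -0.48 ± 0.19 and Tfap2d -1.33 ± 0.54. Some rested on a single unstressed LacZ library: Ttc29 was -0.29 without replicate 6, Tfap2d -0.59 without replicate 4 and Gcc2 -0.55 without replicate 1. None of these passed (adjusted p = 1 for each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

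Glucocorticoid target genes, which are induced by stress hormones in many tissues, were close to their unstressed level in LacZ libraries, with 0.05 ± 0.18 (SE) for Fkbp5, 0.15 ± 0.12 for Sgk1 and 0.05 ± 0.18 for Tsc22d3, and the list had 17 of 26 members above 0 (median 0.05, adjusted p = 0.616 by camera). The activity markers Fos and Arc had 0.05 ± 0.28 and 0.44 ± 0.72, and immediate early genes had 20 of 28 above 0 (median 0.05, adjusted p = 0.616 by camera). Without 1 library these medians were 0.005 (LacZ stressed replicate 2) and -0.02 (LacZ stressed replicate 1). In the Slit and Robo family 12 of 13 members lay below 0 (median -0.22, -0.15 without LacZ unstressed replicate 7, adjusted p = 0.132 by camera), with -0.30 ± 0.43 for Slit1 (0.07 without LacZ unstressed replicate 1), -0.28 ± 0.29 for Slit2, -0.35 ± 0.24 for Slit3, -0.20 ± 0.23 for Robo1, -0.26 ± 0.31 for Robo2, 0.55 ± 0.45 for Robo3 and -0.07 ± 0.36 for Robo4. Genes of RNA interference (11 of 12 below 0) and monoamine and acetylcholine receptors (25 of 30 below 0) had the same adjusted p of 0.132 by camera. After adjustment edgeR, DESeq2 and voomWithQualityWeights called 0 of 19171 genes, with 77, 123 and 681 at an unadjusted p under 0.05. The edgeR number was 214 without LacZ stressed replicate 4, 152 without LacZ unstressed replicate 4, 134 without LacZ stressed replicate 7 and 125 without LacZ unstressed replicate 1, and no list passed in any of these fits.

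Under the knockdown label, stressed and unstressed libraries differed by the smallest p in the same bone genes of knockdown stressed replicate 2. Log2 fold changes were 5.93 ± 1.40 (SE) for Mmp13, 5.62 ± 1.56 for Ibsp, 4.97 ± 1.40 for Col1a1, 3.93 ± 1.04 for Atp6v0d2, 3.61 ± 0.94 for Ctsk, 3.17 ± 0.84 for Col1a2, 2.52 ± 0.75 for the tenascin gene Tnn and 1.63 ± 0.49 for Phex, a peptidase gene of bone. Without that library they were 0.48, -1.75, -1.17, 0.26, -0.22, -0.17, 0.13 and 0.54 in the same order. The values for Ibsp and Col1a1 then lean on knockdown unstressed replicate 6, which had 3.02 and 10.3 CPM of these genes. Mmp9 had 4.93 (95% confidence interval from 2.27 to 7.60), and -0.63 without it. Fam13c (chromosome 10, 70440481 to 70558736) differed from these: it had -0.40 ± 0.13, below the unstressed mean in 7 of 7 libraries, and -0.43 without replicate 2. The adjusted p was 1 for these 10 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Adjusted over the list alone, 5 genes of the extracellular matrix list (Col3a1, Mmp9, Tnc, Col1a2 and Col1a1) and 3 of the meninges and fibroblast list passed, against 0 over all genes. Mmp9, Col1a2 and Col1a1 rested on knockdown stressed replicate 2, as given above. Values of Col3a1 and Tnc without that library are not given here.

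In the same comparison, Slit1 had -0.50 ± 0.43 (SE), which was -0.15 without knockdown unstressed replicate 2, Slit2 -0.17 ± 0.29, Slit3 -0.35 ± 0.24, Robo1 -0.27 ± 0.23, Robo2 -0.26 ± 0.31, Robo3 0.32 ± 0.45 and Robo4 -0.37 ± 0.36. Stress hormone targets had 0.16 ± 0.18 for Fkbp5, 0.01 ± 0.12 for Sgk1 and 0.26 ± 0.18 for Tsc22d3, and the activity genes 0.08 ± 0.28 for Fos and 0.14 ± 0.72 for Arc. Glutamate receptors had 22 of 22 members below 0 (median -0.31), the Slit and Robo family 12 of 13 (median -0.26), axon guidance genes 38 of 49 (median -0.15), monoamine and acetylcholine receptors 21 of 30 (median -0.09) and RNA interference genes 10 of 12 (median -0.13), each with an adjusted p of 0.0658 by camera. The medians were -0.19 for glutamate receptors without knockdown unstressed replicate 7, -0.02 for monoamine and acetylcholine receptors without knockdown stressed replicate 4, and -0.14 for the Slit and Robo family, -0.10 for axon guidance and -0.09 for RNA interference without knockdown unstressed replicate 2. Without knockdown stressed replicate 2 the number of lists past the threshold was 5 (smallest adjusted p = 0.0390 by camera). Interferon response genes had 36 of 38 members above 0 (median 0.35, adjusted p = 0.378 by camera) and oligodendrocyte and myelin markers 18 of 19 below 0 (median -0.47, adjusted p = 0.332 by camera), with medians of 0.21 without knockdown stressed replicate 4 and -0.13 without knockdown unstressed replicate 7. Genes past adjustment numbered 0 of 19171 by edgeR, DESeq2 and voomWithQualityWeights, with 343, 473 and 951 at an unadjusted p under 0.05. The edgeR number was 609 without knockdown unstressed replicate 6, 533 without knockdown stressed replicate 2 and 223 without knockdown stressed replicate 5.

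Averaged over both viruses, 5 of the 44 gene groups passed, all of them lower in stressed mice, while 0 single genes passed. Glutamate receptors, the main excitatory receptors of cortex, fell with 22 of 22 members below 0 (median log2 fold change -0.27, adjusted p = 0.0365 by camera), among them, with the smallest unadjusted p, the NMDA receptor genes Grin3a at -0.27 ± 0.10 (SE) and Grin2b at -0.30 ± 0.11 and the AMPA receptor gene Gria1 at -0.30 ± 0.12, while the kainate receptor gene Grik2 lay furthest below 0 at -0.42 ± 0.27. The Slit and Robo family list fell with 12 of 13 members below 0 (median -0.23, adjusted p = 0.0340 by camera), including Slit1 at -0.40 ± 0.30 (-0.21 without LacZ unstressed replicate 1), Slit2 at -0.23 ± 0.20, Slit3 (chromosome 11, 35121224 to 35708507) at -0.35 ± 0.17, Robo1 at -0.23 ± 0.16, Robo2 at -0.26 ± 0.22, Robo4 at -0.22 ± 0.25 and the Robo signalling gene Srgap3 at -0.25 ± 0.14, with Robo3 the exception at 0.44 ± 0.32. Its members include genes other than Slits and Robos, such as Nell2, Flrt3, Dag1 and Dcc, so the call is not one of the Slit and Robo genes alone. Other axon guidance genes fell with 39 of 49 members below 0 (median -0.18, adjusted p = 0.0477 by camera), among them the ephrin gene Efnb2 at -0.22 ± 0.09, the semaphorin gene Sema6a at -0.22 ± 0.09 and the plexin gene Plxna4 at -0.25 ± 0.12. Monoamine and acetylcholine receptors fell with 23 of 30 below 0 (median -0.15, adjusted p = 0.0340 by camera), with the nicotinic receptor gene Chrna7 at -0.20 ± 0.11 and the serotonin receptor gene Htr4 at -0.47 ± 0.29. The RNA interference machinery fell with 11 of 12 below 0 (median -0.10, adjusted p = 0.0340 by camera), with Ago4 at -0.12 ± 0.08 and Tnrc6c at -0.14 ± 0.08. No member of these lists passed singly, adjusted over all genes or adjusted over the list alone.

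These 5 calls rested on the setting and on single libraries. None passed with fry (smallest adjusted p = 0.0721), with the oligodendrocyte and striatal list means as covariates (smallest adjusted p = 0.0539 by camera) with the GC trend removed (smallest adjusted p = 0.229 by camera) or with the places in the accession order as blocks (smallest adjusted p = 0.0979 by camera). With the GC trend removed the medians were -0.21 for the Slit and Robo family, -0.22 for glutamate receptors, -0.14 for monoamine and acetylcholine receptors, -0.10 for RNA interference and -0.11 for axon guidance. Of the 5 only that of axon guidance moved by over 1.5 times. With the blocks they were -0.21, -0.20, -0.09, -0.09 and -0.10 in the same order. The number of lists past the threshold was 0 without LacZ unstressed replicates 1 or 5, LacZ stressed replicates 4 or 7, knockdown unstressed replicate 2 or knockdown stressed replicate 1, 1 without knockdown unstressed replicate 5, 2 without knockdown unstressed replicate 6, and 3 without replicate 7 of LacZ unstressed, knockdown unstressed or knockdown stressed. Genes of voltage-gated sodium, calcium and HCN channels had 24 of 25 members below 0 but did not pass (adjusted p = 0.0911 by camera). Other gene groups leaned one way with stress without passing: cell cycle genes had 25 of 25 members above 0 (median 0.39, adjusted p = 0.318 by camera), cytokines, chemokines and T cell genes 25 of 26 above 0 (median 0.44, adjusted p = 0.334 by camera, or 0.54 and 0.102 without LacZ stressed replicate 4), and oligodendrocyte and myelin markers 17 of 19 below 0 (median -0.29, adjusted p = 0.328 by camera). The mean of the cytokine list differed by 0.43 log2 CPM, by 0.70 without LacZ stressed replicate 4 and by 0.27 without knockdown unstressed replicate 5. No immune list was entered as a covariate. How far the 5 lower lists follow the content of immune cells in the tissue was therefore not tested. The GC slope was 0.02 ± 0.78 and 0.01 ± 0.76 in LacZ unstressed and stressed libraries and -0.02 ± 0.83 and -0.01 ± 0.70 in knockdown unstressed and stressed libraries (SD, n = 7). Without both knockdown stressed replicate 2 and LacZ stressed replicate 4 the number of lists was 6. Axon guidance had a median of -0.09 without LacZ unstressed replicate 1, monoamine and acetylcholine receptors -0.08 without knockdown unstressed replicate 1, and the oligodendrocyte list -0.13 without knockdown unstressed replicate 7.

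**Figure D4:**
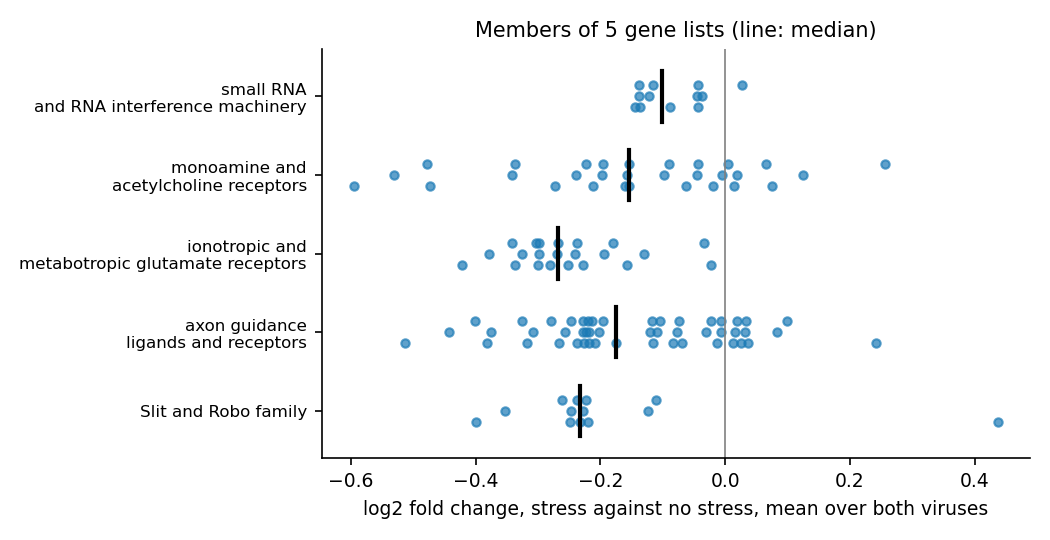
Log2 fold change of stressed against unstressed mice, averaged over both viruses, for each tested member of the 5 gene groups that passed, with the median of each group as a line. Medians lie between -0.27 for glutamate receptors and -0.10 for the RNA interference machinery.

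Of single genes for stress over both viruses, Fam13c had -0.28 ± 0.09 (SE), Gpr176, an orphan receptor gene linked to the circadian clock, -0.44 ± 0.14, Pcsk5, a proprotein convertase gene, -0.46 ± 0.15, Garem1, an adaptor of growth factor signalling, -0.29 ± 0.10 and Grid1, a glutamate receptor delta subunit gene outside the list, -0.37 ± 0.12. Slc35g1 had 0.49 ± 0.16, above the mean of all unstressed libraries in 12 of 14 libraries. The remaining 4 of the 10 smallest p were bone genes, which without knockdown stressed replicate 2 went from 3.42 to 0.69 for Mmp13, from 1.93 to 0.02 for Ctsk, from 1.70 to 0.03 for Col1a2 and from 2.74 to -0.33 for Col1a1. None passed (adjusted p = 1 for each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Stress hormone targets had 0.10 ± 0.12 for Fkbp5, 0.08 ± 0.08 for Sgk1 and 0.16 ± 0.13 for Tsc22d3, and the activity genes 0.06 ± 0.20 for Fos and 0.29 ± 0.51 for Arc. Adjusted over the list alone, Col1a2 and Col1a1 passed in the meninges and fibroblast list at an adjusted p of 0.0486 by edgeR with Benjamini-Hochberg, against 0 over all genes. Both are among the bone genes above, at 0.03 and -0.33 without knockdown stressed replicate 2. At an unadjusted p under 0.05 there were 424 genes by edgeR, 606 by DESeq2 and 1279 by voomWithQualityWeights, each with 0 of 19171 after adjustment. Evenly spread p would give 959, and 46 of 100 splits of the stress labels, the real one included, gave 424 genes or more by edgeR. The edgeR number was 728 without LacZ stressed replicate 4, 667 without knockdown unstressed replicate 6 and 659 without LacZ unstressed replicate 4.

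The interaction tested whether the response to stress differed between the viruses. Its smallest p were again those of bone genes of knockdown stressed replicate 2, with log2 differences of 6.95 ± 2.18 (SE) for Ibsp, 5.09 ± 1.72 for Mmp9, 5.02 ± 1.75 for Mmp13, 4.36 ± 1.48 for Atp6v0d2, 3.35 ± 1.24 for Ctsk, 2.95 ± 1.12 for Col1a2 and 1.87 ± 0.69 for Phex, which were -0.43, -0.48, -0.43, 0.69, -0.47, -0.39 and 0.77 without it. Tfap2d had 2.09 ± 0.79, the meiotic gene Hormad1 1.79 ± 0.68 and the mitochondrial ribosome gene Mrps23 -2.09 ± 0.80, all at group means of 1.24 CPM or less. Tfap2d was 1.35 without LacZ unstressed replicate 4 and Mrps23 -1.17 without LacZ stressed replicate 7. The 10 genes did not pass (adjusted p = 1 for each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Slit and Robo genes had -0.21 ± 0.60 for Slit1 (0.15 without knockdown unstressed replicate 2), 0.11 ± 0.41 for Slit2, -0.07 ± 0.32 for Robo1, -0.23 ± 0.64 for Robo3, -0.30 ± 0.51 for Robo4, -0.002 ± 0.33 for Slit3 and -0.004 ± 0.44 for Robo2. Stress and activity genes had 0.11 ± 0.25 for Fkbp5, -0.14 ± 0.16 for Sgk1, 0.22 ± 0.26 for Tsc22d3, 0.03 ± 0.39 for Fos and -0.30 ± 1.02 for Arc. The glial and interferon genes had 0.12 ± 0.57 for Aif1, -0.15 ± 0.88 for Cd68 and -0.98 ± 0.98 for Isg15. Oligodendrocyte and myelin markers had 18 of 19 members below 0 (median -0.31) and striatal markers 18 of 18 above 0 (median 0.52), both with an adjusted p of 0.659 by camera, the smallest of any list. Both turned on a single library, with medians of 0.08 for oligodendrocytes without knockdown unstressed replicate 7 and -0.09 for striatal markers without knockdown stressed replicate 7. Genes past adjustment numbered 0 of 19171 by edgeR, DESeq2 and voomWithQualityWeights, with 68, 73 and 584 at an unadjusted p under 0.05. With a median standard error of 0.43 per gene, differences of the size seen for most named genes were not detectable at this spread.

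Effects were also compared across the 19171 genes, which are not independent replicates. The log2 fold changes of the knockdown label without and with stress, which share no library, correlated with r = 0.311, and this was 0.0551 without LacZ unstressed replicate 1. Those of stress under LacZ and under the knockdown label, which share no library either, correlated with r = 0.352, and this was 0.188 without LacZ unstressed replicate 7. The knockdown label without stress and stress under LacZ share the 7 LacZ unstressed libraries and correlated with r = 0.447 and a covariance of 0.0266. Simulated unchanged groups against the same controls gave a median r of 0.502 and a median covariance of 0.0755. Each gene was drawn separately there, so differences across whole libraries were missing. Regrouped labels of the same libraries keep them and gave a median r of 0.539 (from -0.589 to 0.954) and a median covariance of 0.057 (from -0.168 to 0.665). The observed values lay within these ranges. With the controls split into separate sets the real data had a median r of -0.354 (from -0.738 to 0.125 over 70 splits) and a median covariance of -0.0488.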

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

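Chosen only after the result was seen were the tests of the first component against GC content and against the groups, the test of knockdown with stress for the bone genes, the 3 tests on Slit1, and the splits within places of the accession order. Over 23 measures in 4 groups, 92 tests for a single library far from the rest of its group gave 7 marks in 6 libraries, where chance marks about 1 group in 20, or 4.6 here. The measures are not independent. The bone list was made after its high library had been seen, so its mark cannot be set against chance.

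The first pattern was the component that held 58.8% of the variance between libraries. The tables argued against gene span as its source, since the loading of a gene had a partial correlation of -0.256 with log10 span at fixed GC against 0.770 with GC at fixed span, and against the design, since the 4 groups held 0.185% of its variance. The GC slope of the libraries from alternate genes and the component computed from the other genes correlated at 0.996. Both sets of genes come from the same libraries, so any difference across whole libraries would show in both. The value cannot tell a GC bias from another source that follows GC. Removing the GC trend took away 36.5% of the variance, and the first component of what was left held 35.8%. Whether RNA quality, amplification, dissection or handling in the accession order, whose 7 places held 70.1% of the component with group means removed, set the slope was not tested, and lanes were not given in the sources used here.

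The second pattern was the bone genes of knockdown stressed replicate 2, whose bone list reached a mean of 1.62 log2 CPM and lay apart from its group. Knockdown together with stress was argued against, because the other 6 libraries of the group differed from the other groups by -0.0292 log2 CPM in this list (exact permutation p = 0.560) against an excess of 1.495 in the single library. Bone in the punch may account for it: of 12 measured markers of bone cells that had not been looked at before, 12 were highest in this library, where chance gives 3.57% each, although Cthrc1 rested on 1 read there and Runx2 had a median of 49.4 CPM in the other libraries. Marrow may have come with it, since 8 of 12 granulocyte markers were highest there, such as S100a9 at 10.2 CPM against 1.14 in the next library, but Elane rested on 1 fragment, Fcnb on 6 and Mmp8 on 1.75 against 1.45 CPM, and Chil3 (8.23 against 52.0 CPM), Prtn3 (0.181 against 1.40), Ctsg (0.0907 against 0.309) and Cebpe were higher elsewhere. Skeletal muscle markers were highest there for 1 of 13 genes.

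The third pattern was the missing decrease of Slit1 in the libraries labelled knockdown. With the trend on exonic GC removed, the log2 fold change over both stress states was 0.0202. Its 95% confidence interval from -0.24 to 0.28 allows a reduction of up to 15.4%. This argues against a bias following exonic GC as what hid a decrease. The GC of the counted span, which is mostly intronic, was not measured, so a GC bias in those fragments stayed open. Tissue composition stayed open, since with the oligodendrocyte and striatal means as covariates the value was 0.0529 with an interval from -0.62 to 0.73. Reads from introns could hide a loss of mature RNA and also stayed open, since exons make up 4.13% of the counted span and exonic reads were not counted apart. A wrong virus label, weak knockdown and cells in the punch that the virus did not reach were not tested.

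The total count of knockdown stressed replicate 4, 32 M, was far below that of the other libraries of its group. The striatal marker list stood apart as highest in its group in LacZ unstressed replicate 6 (3.94 log2 CPM), knockdown unstressed replicate 6 (3.96) and knockdown stressed replicate 7 (4.66). Markers of the olfactory and septal region also stood apart as highest in knockdown stressed replicate 7, at 2.48 log2 CPM. The cytokine, chemokine and T cell list stood apart as lowest in LacZ stressed replicate 4, at -0.212 log2 CPM.

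Each comparison was repeated on 100 splits of the same libraries, the real one included. For the gene groups in stress averaged over both viruses, 1 of 100 splits, the real one, gave as many as 5 lists, and the highest other split gave 1. That is the smallest share such a test can give. It was not adjusted over the comparisons, so chance was not excluded for that count. The groups took turns through places 1 to 5 of the accession order, though not after them, and such splits do not keep this order. Stress labels were therefore also exchanged only within a virus and a place: 1 of 100 splits, the real one, gave 5 lists, and the highest other split gave 2. With the places as blocks the real count was 0, which any split reaches, so the splits cannot test that count. In the other 6 comparisons 0 lists passed, a count that any split reaches, and the highest other count was 1 or 2. For single genes the real count was 0 in all 7 comparisons, which any split reaches, so the splits cannot test it. The highest other split called 1852 genes for the knockdown label without stress, 0 with stress, 8773 for its average, 8149 for stress under LacZ, 0 under the knockdown label, 8727 for its average and 6758 for the interaction. Splits that call so many genes point to a structure of the samples other than the groups. At an unadjusted p under 0.05, the real edgeR count was reached in 82 of 100 splits for the knockdown label with stress and 55 for its average. For stress this was 95 under LacZ, 63 under the knockdown label and 46 on average, and for the interaction 100. None of these counts stood out from regrouped labels. Correlations across genes as far from 0 as the real ones came from 47 splits for the knockdown label without and with stress (real 0.311, highest other 0.850). For stress under both viruses there were 43 (real 0.352, highest other 0.839). For the pair with shared controls, 63 splits gave a correlation at least as high, with negative ones not counted by size (real 0.447, highest other 0.954). Chance could therefore not be excluded for any of these.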

How the results depend on the processing

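Fits with the GC trend removed, fits with the accession order as blocks, fits without knockdown stressed replicate 2 and LacZ stressed replicate 4, and gene groups with each library left out were chosen only after the results were seen. The number of genes past an adjusted p under 0.05 was 0 in all 7 comparisons by edgeR, DESeq2 and voomWithQualityWeights, and 0 under every other scaling, count filter, covariate and omitted library and at an adjusted p under 0.1. What set this limit was not tested by varying depth. Of genes changed 2-fold for the knockdown label without stress, edgeR recovered 26.9% in simulated counts at the measured dispersion and 88.1% at 1/10 of it. In thinned real counts it recovered 50.7%, or 94.0% with surrogate variables, a fit that also called 0 genes in the data as deposited. Simulated changes went both ways over all tested genes, and thinned ones only down in genes with higher counts, so the 2 sets of shares are not comparable. At an unadjusted p under 0.05 with a fold change of at least 1.3, the counts were 119 and 149 for the knockdown label without and with stress, 181 for its average, 72 and 261 for stress under LacZ and the knockdown label, 196 for its average and 67 for the interaction, because that threshold carries no adjustment. Named genes kept their value within 1 SE in 4579 of 4816 refitted values, 210 of which changed sign. Of the rest 178 moved by more with the same sign, and 59 changed sign by more than 1 SE, 43 of them in bone genes under DESeq2 or without knockdown stressed replicate 2, alone or with LacZ stressed replicate 4. None passed, and the smallest adjusted p was 0.243 with Benjamini-Hochberg.

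Slit1 passed under no setting, and its sign was not fixed. For the knockdown label with stress (main value -0.12) it was 0.0037 with tissue composition covariates and 0.15 with voomWithQualityWeights, and its range with each library omitted was -0.30 to 0.0583. For the average (main value -0.02) it was 0.0167 with upper-quartile factors, 0.18 with title number above 20 as a covariate, 0.0672 with surrogate variables, 0.0529 with tissue composition covariates, 0.25 with voomWithQualityWeights (SE 0.21) and 0.0202 with the GC trend removed, and omitted libraries gave -0.20 to 0.16. Without stress (main value 0.09) omitted libraries gave -0.27 (without knockdown unstressed replicate 2) to 0.44 (without LacZ unstressed replicate 1). The cause was not tested.

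Gene groups depended on the test. With a preset correlation of 0.01, camera passed 11 and 20 lists for the knockdown label without and with stress, 18 for its average, 16 and 26 for stress under LacZ and the knockdown label, 28 for its average and 12 for the interaction. With the estimated correlation and all libraries only the 5 lists of stress averaged over both viruses held. Of these, 0 passed with fry (smallest adjusted p 0.0721), 0 with tissue composition covariates (0.0539), 0 with the GC trend removed (0.229) and 0 with the accession order as blocks (0.0979). On GC removal the median went from -0.23 (SD 0.20 over members) to -0.21 (SD 0.21) for the Slit and Robo family, from -0.27 (SD 0.10) to -0.22 (SD 0.11) for glutamate receptors and from -0.10 (SD 0.06) to -0.10 (SD 0.06) for RNA interference, while their inter-gene correlations went from 0.0674 to 0.361, from 0.129 to 0.365 and from -0.00839 to 0.175, which widened the error of the test. For axon guidance the median itself shrank from -0.18 (SD 0.16) to -0.11 (SD 0.16), with a correlation from 0.0495 to 0.0675. For monoamine and acetylcholine receptors the median moved little, from -0.15 (SD 0.20) to -0.14 (SD 0.20). Their correlation rose from 0.00626 to 0.0229 over 30 members, and the unadjusted p by camera went from 0.00232 to 0.0104. Without a library the number ranged from 0 to 6 for that average (6 without LacZ unstressed replicate 6). It ranged from 0 to 2 for the knockdown label with stress (2 without replicate 4 of LacZ stressed or knockdown stressed, 1 without replicate 1 of either), from 0 to 5 for stress under the knockdown label (5 without knockdown stressed replicate 2) and from 0 to 2 for the average of the knockdown label (2 without LacZ stressed replicate 4, 1 without replicate 1 of LacZ stressed or knockdown stressed), and stayed at 0 in the other comparisons. Across the 28 omissions the Slit and Robo family passed in 20, axon guidance in 8, glutamate receptors in 18, monoamine and acetylcholine receptors in 20 and RNA interference in 21. Without both libraries that stood apart, the counts were 3 for the knockdown label with stress and 5 for stress under the knockdown label. The cause was not tested for fry, for the covariates and for the single omissions. Leaving out 1 library moved 294 of 308 list medians and 115 of 148 values of named genes by over 1.5 times or across 0, with a change of sign in 156 and 45.

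Of the 3 correlations across genes, the last turned to a median r of -0.354 with the shared controls split into separate sets. All 3 kept their sign under the other alternatives. In the order of the report they ran from 0.214 to 0.410, from 0.254 to 0.499 and from 0.350 to 0.494 over scaling, filter, covariates, rank correlation and fits without both libraries that stood apart, and from 0.0551 to 0.411, from 0.188 to 0.412 and from 0.328 to 0.648 with each library omitted, with the lowest of the first and the highest of the last without LacZ unstressed replicate 1.

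Replicate numbers came from the accession order and not from a label, so they name libraries and do not pair them. Libraries at the same place deviated from their group means with a mean correlation of 0.322 against -0.0511 at other places. In 4 of 7 places every correlation was over 0.1, but the lowest at a shared place was -0.699. Of 28 libraries, 9 lay closest to one of their own place, a number for which no chance value was computed. As blocks the places changed no count of genes (0 in all 7 comparisons by edgeR, with 255, 154, 122, 538, 58, 395 and 809 at an unadjusted p under 0.05 for the knockdown label without and with stress, stress under LacZ and the knockdown label, the interaction, and the averages of the knockdown label and of stress). They changed no count of lists but that of stress averaged over both viruses, from 5 to 0.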

Other observations

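Tests of relations between gene lists across libraries and of Slit1 with the GC trend removed were chosen only after the results were seen. Transcripts of immune cells varied over a wide range between mice of the same group. Cd8a, a marker of cytotoxic T cells, ran from 0.0453 to 27.3 CPM over the 28 libraries, Gzmb from 0.408 to 133.5 CPM and Saa3 from 0.0453 to 83.8 CPM. With the GC trend removed, the mean of the cytokine, chemokine and T cell list moved together with antigen presentation (Pearson's r = 0.959, Spearman's rho = 0.930), complement and phagocytosis (r = 0.940, rho = 0.927), cell cycle genes (r = 0.959, rho = 0.947), reactive astrocyte genes (r = 0.893, rho = 0.852) and microglial markers (r = 0.804, rho = 0.762). Each Pearson r had a permutation p of 1.00e-05, the smallest the permutations can give, and a Benjamini-Hochberg adjusted p of 1.75e-05 over 14 relations. For these rho the permutation p was 1.00e-05, or 2.00e-05 for microglial markers. Without LacZ stressed replicate 4 and LacZ unstressed replicate 7, the libraries farthest from the median, r was 0.940, 0.928, 0.931, 0.813 and 0.781 in the same order. Interferon response genes followed less closely (r = 0.718, permutation p = 4.00e-05, adjusted p = 6.22e-05 by Benjamini-Hochberg, rho = 0.625, permutation p = 4.40e-04, and r = 0.507 without those libraries).

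Synaptic vesicle genes moved against the immune list (r = -0.639, permutation p = 2.30e-04, adjusted p = 3.22e-04 by Benjamini-Hochberg, rho = -0.690, permutation p = 8.00e-05, and r = -0.580 without the 2 farthest libraries), and so did cholesterol synthesis (r = -0.584, permutation p = 8.90e-04, adjusted p = 0.00113, rho = -0.497, permutation p = 0.00754), whose r was -0.390 without those libraries. Oligodendrocyte and myelin markers did not move with it (r = 0.003, permutation p = 0.988, rho = -0.0679, permutation p = 0.730), nor did meninges and fibroblast markers (r = -0.075, permutation p = 0.697, rho = 0.0728, permutation p = 0.711). With group means removed, r was 0.960 for antigen presentation, 0.936 for complement, 0.960 for cell cycle, -0.591 for synaptic vesicle genes and -0.564 for cholesterol synthesis, so these relations ran within groups. Mitochondrial genes held 5.78 ± 2.13% of counts in LacZ unstressed, 6.40 ± 2.45% in LacZ stressed, 6.67 ± 4.22% in knockdown unstressed and 5.70 ± 1.67% in knockdown stressed libraries (SD, n = 7). For stress averaged over both viruses, reactive astrocyte genes had 23 of 25 members above 0 (median 0.26) and estrogen and progesterone signalling genes 11 of 16 below 0 (median -0.10), both with an adjusted p of 0.328 by camera. Their medians were 0.15 without LacZ stressed replicate 2 and -0.01 without knockdown unstressed replicate 7.

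With the GC trend removed, Slit1 in log2 CPM was lower with stress than the unstressed mean in 7 of 7 libraries labelled knockdown (exact permutation p = 0.049) and in 6 of 7 LacZ libraries (exact permutation p = 0.201), against exact p of 0.350 and 0.547 as counted. These are 2 of 4 such comparisons of Slit1, without adjustment, and the knockdown label gave exact p of 0.614 and 0.572. As counted, the log2 fold change with stress leaned on single unstressed libraries: it went from -0.30 to 0.07 under LacZ without LacZ unstressed replicate 1, from -0.50 to -0.15 under the knockdown label without knockdown unstressed replicate 2, and from -0.40 to -0.21 on average without LacZ unstressed replicate 1. The tests with the GC trend removed were not repeated with libraries left out, so a decrease of Slit1 with stress was not established.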
